A study of Homo sapiens with 2 samples.

How the data were processed

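Crosslinking and immunoprecipitation followed by sequencing (CLIP-seq) had been run on 2 libraries from HEK293T cells, a human embryonic kidney line, that carried a doxycycline-inducible FLAG-tagged DHX29. Per the labels' protocols, the cells received 40 ng/ml doxycycline for 24 hours and were crosslinked with ultraviolet light at 254 nm (300 mJ/cm²). The lysate was cut with RNase I at 0.01 units/ml for 5 minutes and precipitated through the FLAG tag. Complexes above 130 kDa were taken from a gel, and cDNA of 10 to 200 nt was amplified over 18 PCR cycles. Both libraries belong to 1 group, and no input, untagged or other control library was analysed here. The library names of both samples carry the word DMSO, while the treatment label gives doxycycline alone.

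The authors deposited 1 file per library with a whole-number read count for each of 78899 Ensembl gene IDs, unscaled and not pooled, per the file headers and the values. The submitters' processing notes name fastp, cutadapt 3.7, UMI-tools 1.1.4, STAR 2.7.0a and featureCounts 2.0.3, and the human build GRCh38 (hg38), without giving the role or settings of any of them. The annotation release, the strand setting of the counting, the treatment of reads with several hits and the number of reads sequenced are not given in the sources used here. Each of these could change the counts. Whether the counts keep reads of a gene apart from those of an overlapping antisense gene is not known. Whether the reads were counted on the strand of the RNA was not tested.

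The counts summed to 3044 in replicate 1 and 1890 in replicate 2. One count was therefore worth 329 CPM (the count scaled to a library of 1e6) in replicate 1 and 529 in replicate 2. A count of 0 allows a share of up to 0.0986% of the counts in replicate 1 and 0.159% in replicate 2 (3 counts of the total). Shares are given with Wilson 95% intervals unless named otherwise. Intervals and limits cover counting error only. The sources do not say whether the 2 libraries came from separate cultures, so the spread between them may be technical.

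The count files hold Ensembl IDs alone. The table of 59792 RefSeq genes used here (GRCh38.p14) has a column for Ensembl IDs with 0 filled cells, so none of the 78899 IDs could be matched through it. Gene symbols, RNA classes, gene lengths and coding sequences were therefore not analysed here. The following results had been laid out before the data were examined and were not run: the composition by RNA class, the level of DHX29, the fixed gene lists and cell type markers, and the relation of levels to transcript features and codon use. The rule for naming genes asked for DHX29, for the leading IDs by mean CPM overall and within RNA classes and gene lists, and for the 5 IDs with the largest ratio in each direction among those past the between-library test with at least 50 summed counts. Since no ID could be paired with a symbol, only 4 IDs are printed. They are the 2 with the highest mean CPM and the 2 past the between-library test. One of those 2, ENSG00000065183, has fewer than 50 summed counts and so falls outside the rule, and it was chosen after its values were seen.

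With 1 group there is no contrast between conditions. The 2 libraries were compared with each other over the 51 IDs with at least 10 summed counts. Library sizes were scaled by TMM over these IDs (edgeR 4.0.16 in R 4.3.3). A two-sided exact binomial test per ID, with Benjamini-Hochberg adjustment at 0.05, asked whether the counts split between the libraries as the scaled sizes do. It compares these 2 libraries only. A chi-square statistic summed the same deviations. Its p came from a binomial simulation test, in which each ID's summed count was split at random by the scaled sizes 10000 times. These draws do not hold the library totals fixed. Pearson and Spearman correlations of log2(CPM + 1) were taken across IDs and carry no p, because IDs are not independent replicates. The common dispersion was estimated by edgeR with both libraries as 1 group. The number of IDs seen in both libraries was set against 10000 random sharings of all counts at the real library totals. The random sharings and Turing's estimate of unseen IDs were added after the counts had been seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

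The procedures were tested on simulated data over 100 runs, with Poisson counts at the real totals. All these runs scaled the libraries by total counts, so the TMM scaling used on the data was not tested. Each ID's mean came from its real summed count, so IDs without a count stayed at 0. The 200 IDs changed between the libraries were drawn from the IDs with most counts. Among changed IDs that reached 10 summed counts, the binomial test recovered 25.2% of 2-fold, 58.5% of 4-fold, 76.9% of 8-fold and 91.8% of 16-fold differences. On average, 8.48, 8.89, 16.25 and 26.25 changed IDs per run reached 10 summed counts at these folds. The other changed IDs were not tested, so recovery over all changed IDs was lower. The binomial test called 2.10% of the unchanged IDs tested beside the changed ones, with total counts as the scaling. With no ID changed, it called 0.02 IDs per run on average, and at most 1. The simulated counts varied by Poisson noise alone, so these rates do not carry over to libraries that vary more, as these 2 did. The random sharings held the simulated overlap within their central 95% in 38 of 40 pairs of equal composition. Alternatives covered the scaling (DESeq2 1.42.0 size factors, total counts), the minimum of summed counts (1 and 50), a pseudocount of 0.1 CPM, edgeR's exact test with the estimated dispersion, and leaving out each library.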

Results

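The series recorded which transcripts were recovered with FLAG-DHX29 from HEK293T cells. DHX29 is a DExH-box helicase that binds the small ribosomal subunit and helps it scan structured leader sequences of mRNAs. Its 2 libraries formed a single group, so the data give the level of each Ensembl gene ID in the precipitate and the agreement between replicate 1 and replicate 2. Without an input or control library, a level combines the abundance of the RNA, its length and its recovery, and enrichment over background was not analysed here. The strand setting of the counting is not given in the sources used here, so a level stands for the counts listed under an ID, whether or not the reads came from that gene's own strand.

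Few genes carried counts. Replicate 1 held 3044 counts on 1578 of the 78899 listed IDs (2.00%), and replicate 2 held 1890 counts on 1073 IDs (1.36%). Most of these IDs had exactly 1 count in their library, namely 1142 IDs or 72.4% in replicate 1 and 807 IDs or 75.2% in replicate 2. Only 29 IDs reached 10 counts in replicate 1 and 20 in replicate 2, and 16 did so in both. Over both libraries together 2224 IDs had a count, of which 1549 (69.6%) had a summed count of 1. The 51 IDs with at least 10 summed counts held 27.3% of the 4934 counts.

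The counts were spread over many IDs without a dominant ID. RNA classes were not analysed here, and the treatment of reads with several hits is not given. The counts therefore do not show whether 1 RNA dominated the precipitate. The ID with the highest mean share, ENSG00000163565, took 53 counts in replicate 1 (1.74%, 95% interval 1.33 to 2.27) and 31 in replicate 2 (1.64%, 1.16 to 2.32), a mean of 1.69% ± 0.0714 (SD, n = 2). ENSG00000303745 followed with 41 counts in replicate 1 (1.35%, 0.994 to 1.82) and 37 in replicate 2 (1.96%, 1.42 to 2.69), a mean of 1.65% ± 0.432 (SD, n = 2). The intervals of the 2 IDs overlapped in each library, so their order was not resolved at these totals. The 15 IDs with the highest mean CPM together took 16.03% of the counts in replicate 1 (14.8 to 17.4) and 17.1% in replicate 2 (15.5 to 18.9), a mean of 16.6% ± 0.748 (SD, n = 2). Their counts ran from 11 to 73 in replicate 1 and from 5 to 37 in replicate 2. Of these 15 IDs, 14 did not pass the binomial test for a difference between the libraries. Not passing does not show equal levels, and the lowest unadjusted p among the 14 was 0.011 (exact binomial test). The lists of the 15 leading IDs of each library shared 12 IDs, with ties at the last place of the list of replicate 2 broken by file order.

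At these totals, a large share of further counts would fall on IDs not yet seen. The number of reads sequenced is not given, so the low totals cannot be put down to sequencing depth. By Turing's estimate, which takes the share of counts on IDs seen once, 37.5% of further counts from the population of replicate 1 would fall on IDs not yet seen, and 42.7% from that of replicate 2. In replicate 2, 746 of the 1890 counts (39.5%, 37.3 to 41.7) fell on IDs with no count in replicate 1, an interval that holds the 37.5% estimated from replicate 1. In replicate 1, 1418 of the 3044 counts (46.6%, 44.8 to 48.4) fell on IDs with no count in replicate 2, an interval that lies above the 42.7% estimated from replicate 2. These intervals leave out the error of the estimates themselves and take counts on the same ID as independent. Neither comparison is therefore a test of agreement. An ID at 0 was therefore below detection at these totals, which does not show that its transcript was absent from the precipitate.

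Among the 51 IDs with at least 10 summed counts, 2 differed between the libraries beyond counting error, 1 in each direction, and 7 had an unadjusted p under 0.05. ENSG00000301546 had 73 counts in replicate 1 (2.40%, 1.91 to 3.00) and 5 in replicate 2 (0.265%, 0.113 to 0.618). It was 8.71-fold higher in replicate 1 after TMM scaling (exact 95% interval 3.57 to 27.6; adjusted p = 2.1e-08, exact binomial test). It ranked first in replicate 1 and 34th in replicate 2, with a mean share of 1.33% ± 1.51 (SD, n = 2). ENSG00000065183 had 0 counts in replicate 1 and 14 in replicate 2 (0.741%, 0.442 to 1.24). After TMM scaling its level in replicate 2 was 7.83-fold above the limit of 3 counts in replicate 1. With the counting error of both libraries it was at least 5.56-fold higher in replicate 2 (exact 95% bound; adjusted p = 2.6e-05, exact binomial test). Neither call held in edgeR's exact test with the dispersion estimated from the same libraries (adjusted p = 0.086 for each). That dispersion takes in the differences under test (0.150 with the 2 IDs, 0.048 without them). The loss of the calls therefore does not show that the libraries agree on these IDs. These tests compare 2 libraries of 1 group and not conditions.

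**Figure D1:**
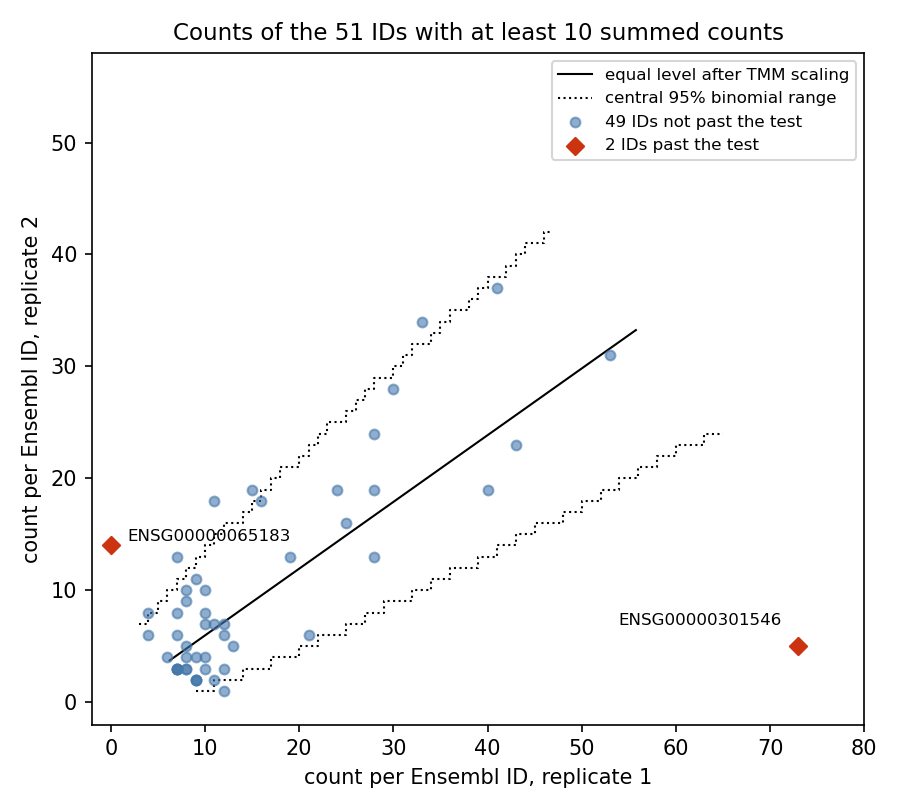
Counts in replicate 1 (x axis) against counts in replicate 2 (y axis), with 1 point for each of the 51 IDs with at least 10 summed counts; the line marks equal levels after TMM scaling and the dotted lines the central 95% binomial range. The diamonds are the 2 IDs past the binomial test, at 73 against 5 counts and at 0 against 14 counts, while the other 49 IDs did not pass it.

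Over the 51 IDs together the libraries differed by more than independent counting noise. Their files also held different totals, and they were counted as 2 samples. The test sets the libraries against counting noise alone and does not measure whether they differ more than replicates usually do. The chi-square statistic was 2.62 per degree of freedom (p = 0.0001, binomial simulation test, the smallest p that 10000 draws can give). Without ENSG00000301546 and ENSG00000065183 it was 1.59 per degree of freedom over the other 49 IDs (p = 0.0045, binomial simulation test), an alternative chosen after the values were seen. The edgeR common dispersion corresponded to a biological coefficient of variation of 38.7%, and of 21.9% without these 2 IDs. Across the 51 IDs, log2(CPM + 1) in the libraries correlated with Pearson's r = 0.21 and Spearman's rho = 0.53. Both turned negative with other minimums of summed counts, to -0.53 and -0.25 with a minimum of 1 and to -0.69 and -0.26 with a minimum of 50 (8 IDs). A minimum on the summed count itself pulls correlations down, since an ID low in 1 library must be high in the other to pass. The 8 IDs include ENSG00000301546, at 73 against 5 counts. Pearson's r also rests on the pseudocount, which is far below 1 count, and on ENSG00000065183 at 0 in replicate 1. It was 0.15 with a pseudocount of 0.1 CPM. The negative values therefore do not show that levels run opposite in the libraries. Without the 2 IDs, at the minimum of 10, Pearson's r was 0.68 and Spearman's rho 0.61. Leaving out IDs because they differed by itself makes the libraries look more alike. These values and the lower coefficient of variation are therefore no check of agreement.

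The libraries shared fewer IDs than independent counts from equal compositions would give. Both libraries had a count for 427 IDs (19.2% of the 2224), against a mean of 457 in 10000 random sharings of the counts at the real library totals (central 95% from 436 to 478; two-sided p = 0.0052, permutation test). Lists drawn independently from all 78899 IDs, with each ID equally likely, would share 21.5. IDs differ in level and most had no count in either library, so this value is no test of agreement. Replicate 1 had 1151 IDs of its own and replicate 2 had 646. The number of IDs in replicate 1, 1578, lay within the range of the sharings (1546 to 1608), and that in replicate 2, 1073, lay at the lower edge of its range (1073 to 1135; two-sided p = 0.051, permutation test). By summed count, 122 of 306 IDs with 2 counts were seen in both libraries (39.9%, against 41.8% to 52.9% in the sharings). The classes with 3, 4, 5 to 9 and at least 10 summed counts lay within their ranges. After Benjamini-Hochberg adjustment over the 5 classes, none passed 0.05 (lowest adjusted p = 0.054, permutation test). Before adjustment, the class with 2 counts had p = 0.011 in the permutation test.

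**Figure D2:**
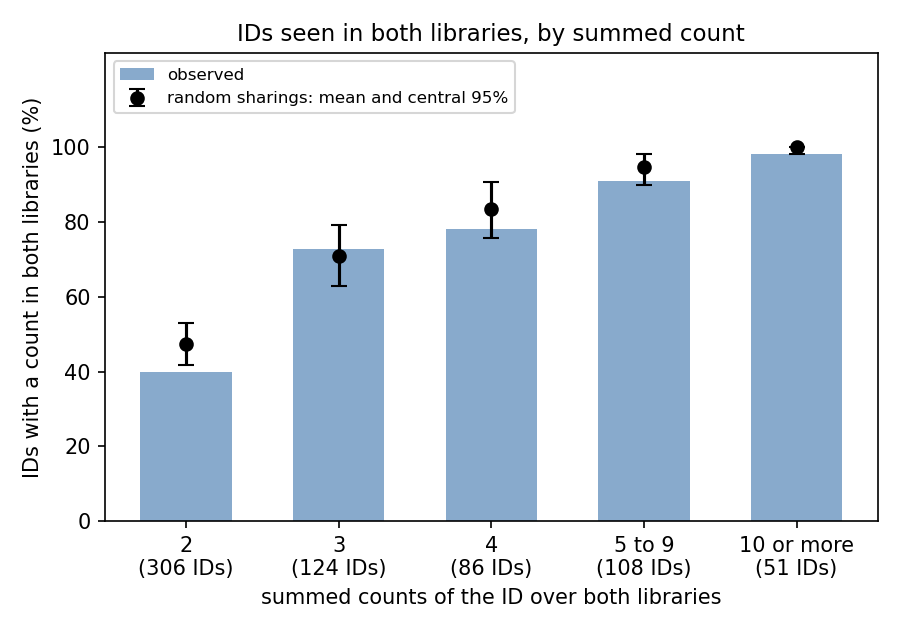
Share of IDs with a count in both libraries (y axis, percent) by the ID's summed count (x axis); bars are the observed shares, and points with error bars the mean and central 95% of 10000 random sharings of the counts. The share rises from 39.9% at 2 summed counts to 98.0% at 10 or more, and only the class with 2 counts lies outside its range.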

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

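The count of IDs that differed between the libraries was 2 under total counts, under DESeq2 size factors and with a minimum of 1 summed count, and these were the same IDs. It was 1 with a minimum of 50 summed counts, where ENSG00000065183 (14 counts) is not tested. It was 0 in edgeR's exact test with the estimated dispersion, where 2 IDs had an unadjusted p under 0.05. That dispersion was estimated with these IDs included. The DESeq2 size factors came out equal for both libraries, because the median count ratio over the IDs seen in both was 1, so they did not correct for depth. The chi-square statistic stayed past its threshold in each alternative run (1.08 to 5.75 per degree of freedom). All these runs reuse the same counts, so they are no independent support. The highest value, 5.75, came with the minimum of 50, over 8 IDs that include ENSG00000301546 at 73 against 5 counts. In the run with DESeq2 size factors (3.59 per degree of freedom) the statistic includes the difference in library totals, so that run adds no support. The correlations depended on the minimum. With a minimum of 1 summed count, Pearson's r was -0.53 and Spearman's rho -0.25, where an ID with 1 summed count is by construction at 0 in the other library. With a minimum of 50 they were -0.69 and -0.26, over 8 IDs that include ENSG00000301546. Without the 2 called IDs, an alternative chosen after seeing the data, r was 0.68 and the coefficient of variation 21.9%. These IDs were left out because they differed, so the closer values are no check of agreement. The 15 leading IDs took 17.1% of the counts without replicate 1 and 16.03% without replicate 2. They were not chosen again for each library, so these are the shares given above and no separate check. Leaving out a library gives no value for the agreement of the libraries. Alternatives that need gene names, classes, lengths or sequences were not run. No paired analysis was possible because there is only 1 group. The low totals limited all single-ID values, with 51 IDs open to testing.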

Other observations

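All tests in this part were chosen after the counts had been seen. For the IDs with exactly 2 summed counts, the outcome looked for was written down before the result for these IDs was computed. That outcome is the complement of the number of these IDs seen in both libraries, so it is not independent of the pattern it was meant to explain.

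The IDs with many counts carried higher Ensembl numbers than those with few. Ensembl gives numbers broadly in the order in which genes enter its annotation. The upper 2 of 5 equal parts of the listed ID numbers, from number 265135 upward, held 31 of the 51 IDs with at least 10 summed counts (60.8%, 47.1 to 73.0), against 625 of the 2173 detected IDs with fewer counts (28.8%, 26.9 to 30.7; odds ratio 3.84, Fisher's exact test p = 3e-06, with IDs taken as independent). The lowest part, which held 39.7% of all detected IDs, held 8 of the 51 (15.7%, 8.17 to 28.0). The parts' shares of counts were similar in both libraries. The fourth part took 25.6% of the counts in replicate 1 (24.0 to 27.1) and 27.0% in replicate 2 (25.1 to 29.1), and the lowest part took 31.0% (29.4 to 32.7) and 31.4% (29.4 to 33.6). No explanation was tested. Whether the reads were counted on the right strand stays open, and it bears on these late-numbered IDs, on the totals of only 3044 and 1890 counts and on what the level of each ID stands for. Testing it needs the strand of each gene, which was not used here.

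Fewer IDs were seen in both libraries (427) than in random sharings of the counts at the real totals (436 to 478). A candidate explanation is that counts of an ID arrived in groups within a library, for example as copies of 1 molecule. Of the 306 IDs with exactly 2 summed counts, 184 had both in 1 library, against 144 to 178 in the sharings. These are all IDs of this class other than the 122 seen in both libraries. The count therefore restates a part of the deficit and is no separate check of the explanation. This class supplies much of the deficit and does not pass adjustment over the 5 count classes (adjusted p = 0.054, permutation test), so it does not decide the matter. Grouped counts and real differences between the libraries cannot be told apart, since both give this excess, and no biological explanation was tested because the design has 1 group.

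The cause of the difference in ENSG00000301546 between the libraries (73 counts in replicate 1 against 5 in replicate 2) was not tested.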
